A study of Mus musculus with 6 samples.

How the data were processed

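Splenic NK cells of healthy (WT, 3 samples) and lymphoma-bearing (Eumyc, 3 samples) C57BL/6J mice were profiled by RNA sequencing. Per the labels' protocols, spleen cells were depleted of B cells with an antibody and beads, enriched with beads against CD49b, and sorted as cells positive for NK1.1 and negative for the T cell receptor beta chain. For the Eumyc samples both the bead-bound and the unbound fraction went into the sort, so this step differs between the groups in every library. Libraries were made with an Illumina TruSeq kit, per the labels' protocols.

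The count table deposited by the authors holds whole-number counts per gene for 50686 Ensembl genes, with each gene's coordinates, symbol and biotype. Per the submitters' processing notes, STAR 2.5.2, HTSeq 0.6.1 and DESeq2 1.10.1 were used with the builds mm10 and GRCm38, 2 names of the same mouse assembly. The annotation release, the strand setting and any read filter are not given in the sources used here, so antisense, overlapping and near-identical genes are read as uncertain. The authors also deposited a table of their own comparison, from which the log2 fold change and the p-value columns were used. It lists 10292 genes, 4 of them with no adjusted p-value, and each reaches at least 3 CPM in some library, while 11676 genes of the count table do so. In the deposited counts 25474 genes had 0 counts in every library, and 15458 passed edgeR's expression filter and held 99.9% of the counts.

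The library totals were 27535702, 36534191 and 16407611 counts in WT and 44456157, 65353739 and 66615602 in Eumyc. Intervals and bounds from counts cover counting error only, since PCR copies were not marked. Mitochondrial genes took 1.05% to 1.19% and the 50 most abundant genes 10.7% to 11.7% of counts in a library. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 8.95 within a group.

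Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter was filterByExpr at its minimum count of 10, scaling used TMM, and the model held the group alone in a quasi-likelihood fit with a two-sided test. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene counted as changed under 0.05. Log2 fold changes are given with standard errors computed from the F statistic. Values in CPM are TMM-scaled with the SD over 3 libraries, and list sums are in CPM of all gene counts without TMM. The common biological coefficient of variation was 0.137.

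Before the data were examined, 34 gene lists were fixed, 23 of NK cell programmes and 11 of other cell types. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Summed CPM of a list was compared between groups with a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3. Named genes followed a rule also fixed in advance. It took the 8 highest and 8 lowest log2 fold changes among changed genes with a mean of at least 10 CPM in the higher group and no overlap between groups, without antigen receptor segments, unnamed genes and pseudogenes. It also took 17 genes whatever their result, up to 3 changed members with the largest log2 fold change of each programme list with a mean of at least 10 CPM, and the 2 most abundant members in Eumyc of each other cell type list. Antigen receptor segments were counted as groups.

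Alternatives fixed in advance were DESeq2 1.42.0, limma 3.58.1 voom with and without sample quality weights, other scalings (DESeq2 size factors, total counts, upper quartile, TMM outside other cell type lists), no filter, a filter of 3 CPM in 3 libraries, a test against a 1.5-fold change, a replicate block and leaving out each library. Thinning all libraries to the smallest total and removing trends with GC content and transcript length were chosen after seeing the data, with lengths from the GENCODE M21 annotation for 99.8% of the tested genes.

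The scripts were tested on simulated counts for the 15458 genes with 200 changed ones, drawn outside the gene lists. The cytotoxic granule and death ligand list was also raised 2-fold. In this simulation of 3 against 3, edgeR recovered 67.2% of genes changed by 1.5-fold, 92.5% of those changed by 2-fold and 100% of those changed by 4-fold, with 4.46% of its calls false. DESeq2 recovered 79.1%, 95.5% and 98.5% with 17.6% of its calls false, and limma-voom 64.2%, 89.6% and 98.5% with 3.09% false. Camera recovered the 1 seeded list and called 0 of the other 32. The simulated genes varied independently and few were changed. In the data 48.8% of genes were called and list correlations were estimated at up to 0.916. These rates therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9.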

Results

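The series measured RNA of natural killer (NK) cells from mouse spleen by bulk RNA sequencing in 6 libraries. NK cells are innate lymphocytes that kill infected and transformed cells. In the Eumyc group, C57BL/6J mice had been inoculated intravenously with Eµ-myc lymphoma, a B cell lymphoma driven by the Myc oncogene, and spleens were taken at day 14 after inoculation. The WT group came from healthy mice of the same strain. Each group had 3 libraries. The 3 WT libraries held 27535702, 36534191 and 16407611 gene counts, and the 3 Eumyc libraries held 44456157, 65353739 and 66615602, so every Eumyc library was deeper than every WT library. The labels did not say whether the 3 samples of a group came from separate animals, so the p-values below measure only the spread between these samples, which could be technical.

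The comparison of the 2 groups asked how the transcripts of splenic NK cells differed between lymphoma-bearing and healthy mice. The Eumyc sort also took cells that the CD49b beads had not bound. The sort and the lymphoma therefore cannot be told apart for any difference below. Genes of cell division were higher in the Eumyc libraries, and the proliferation marker Mki67 went from 64.6 ± 62.3 CPM (SD, n = 3) in WT to 673 ± 115 CPM (SD, n = 3) in Eumyc. The cytotoxic protease Gzmb rose from 638 ± 174 to 2129 ± 227 CPM (SD, n = 3 each), and the inhibitory receptor gene Lag3 rose from 8.57 ± 2.90 to 84.5 ± 5.26 CPM. S1pr1, which encodes a receptor that lets lymphocytes leave tissues, fell and was at 93.2 ± 10.7 CPM in WT and 32.8 ± 1.88 CPM in Eumyc. The pore-forming protein gene Prf1 stood at 1538 ± 20.8 and 1738 ± 220 CPM, and the interferon gene Ifng at 38.9 ± 6.14 and 30.8 ± 6.58 CPM, and neither difference passed the test. Ifng passed without Eumyc replicate 1 (log2 fold change -0.51, edgeR adjusted p = 0.0207), and Prf1 passed without Eumyc replicate 3 (0.28, adjusted p = 0.0253).

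Of 15458 genes tested with edgeR's quasi-likelihood test, 7549 (48.8%) had a Benjamini-Hochberg adjusted p under 0.05, of which 3973 were higher and 3576 lower in Eumyc. Against a change of 1.5-fold, 1828 genes passed, 1260 higher and 568 lower. The CPM values of the groups did not overlap for 9298 genes, or 60.2% of those tested, where chance gives 10% for 3 against 3. The first principal component held 75.7% of the variance and separated the groups, and the second held 9.98% and set WT 3 apart. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.978 to 0.992 within groups and 0.926 to 0.958 between them.

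Coordinates are from the deposited table, on the mouse GRCm38 build, and span the whole gene. Mki67 (ENSMUSG00000031004) lies on chromosome 7 from 135689784 to 135716361, Gzmb (ENSMUSG00000015437) on chromosome 14 from 56258856 to 56262260 and Lag3 (ENSMUSG00000030124) on chromosome 6 from 124904361 to 124911705. S1pr1 (ENSMUSG00000045092) spans 115710433 to 115715072 on chromosome 3, Fos (ENSMUSG00000021250) spans 85473890 to 85477273 on chromosome 12 and Fcgr4 (ENSMUSG00000059089) spans 171018920 to 171029761 on chromosome 1. All 6 are protein-coding genes in the table.

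**Figure D1:**
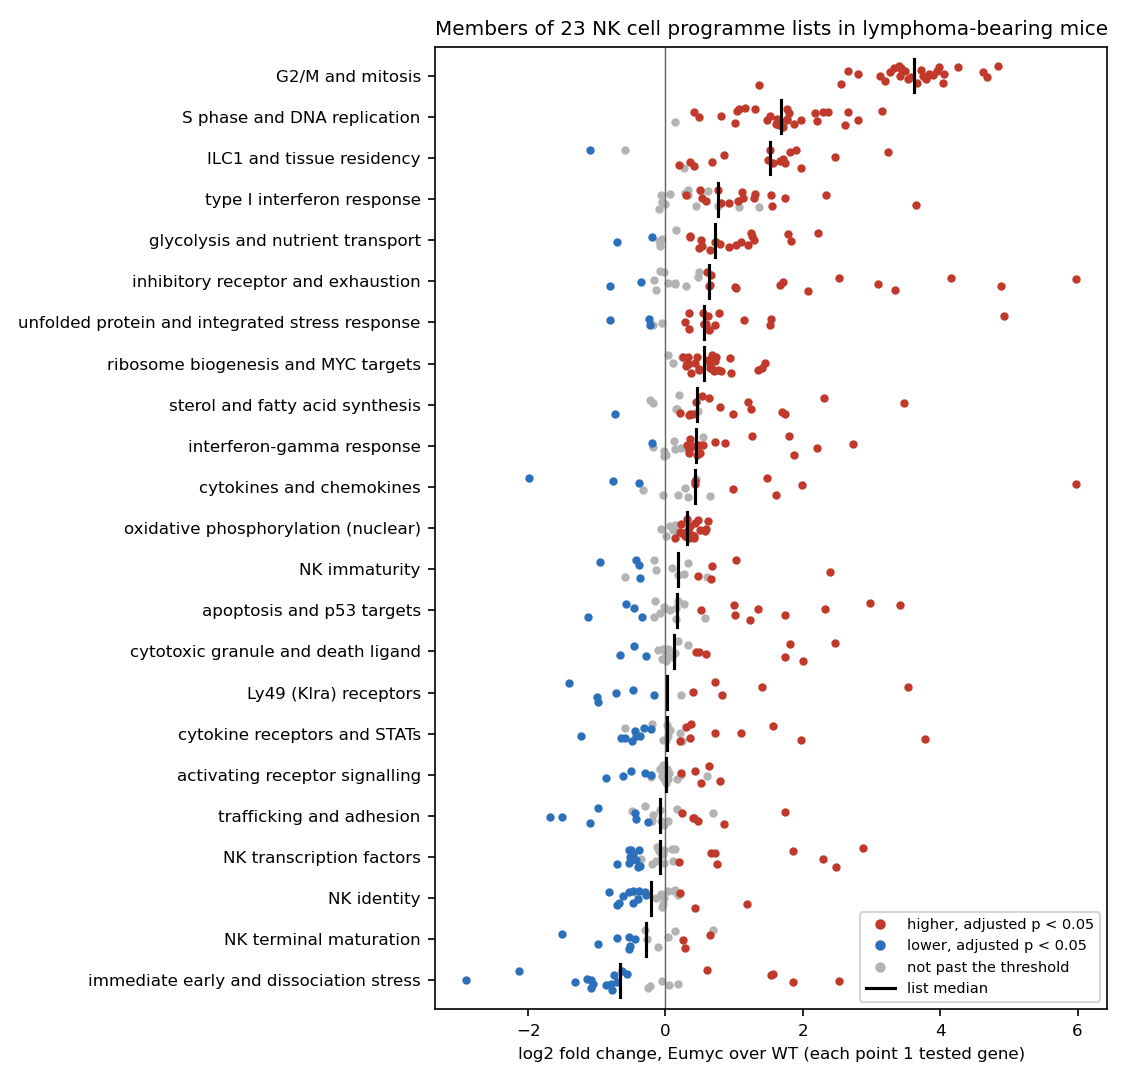
Log2 fold change (Eumyc over WT, horizontal axis) of each tested member of the 23 NK cell programme lists (rows), with the list median as a black bar and members past an edgeR adjusted p of 0.05 in red (higher) or blue (lower). All 30 mitosis genes lie to the right of 0 with a median of 3.61, and the immediate early list has a median of -0.67.

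Gene lists fixed before the data were examined were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01. With this test, 23 of 33 lists passed an adjusted p of 0.05, 20 of them higher and 3 lower in Eumyc. With an estimated correlation 0 lists passed with camera, the smallest adjusted p being 0.0564, although 6 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 24. Under the other 15 alternatives, 19 of the 23 lists passed in every one. The adjusted p of a list with an estimated correlation stands beside its count. This p need not reflect correlation among the genes of the list alone.

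All 30 tested genes of the G2/M and mitosis list rose, over all genes and also when adjusted over the list alone (camera adjusted p = 1.80e-20, and adjusted p = 0.380 with an estimated correlation). The median log2 fold change was 3.61. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 4.84 ± 0.39 (SE) on the log2 scale, the cyclin gene Ccnb1 by 4.69 ± 0.40 and the spindle gene Hmmr by 4.63 ± 0.51. In the S phase and DNA replication list 29 of 30 genes rose and 1, Cdt1, did not pass, with the same 29 adjusted over the list alone (camera adjusted p = 1.51e-12, adjusted p = 0.428 with an estimated correlation). Its median was 1.69, and Rrm2, a subunit of ribonucleotide reductase, rose by 3.15 ± 0.54, Uhrf1 by 2.80 ± 0.59 and Gins2 by 2.65 ± 0.55. WT 3 held more of these transcripts than WT 1 and 2, by a median of 1.67 log2 units over the mitosis list (29 of 30 genes) and 0.82 over the S phase list (30 of 30). Mki67 stood at 31.8, 25.6 and 136 CPM in WT 1, 2 and 3. Without WT 3 the median of the mitosis list was 4.46, the Mki67 log2 fold change was 4.57 in place of 3.42, and those of Rrm2, Uhrf1, Gins2, Ube2c, Ccnb1 and Hmmr were 4.18, 4.01, 3.73, 5.45, 5.34 and 5.59.

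Ribosome biogenesis and MYC target genes rose in 25 of 30 cases, 27 when adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.34e-07, adjusted p = 0.472 with an estimated correlation). Odc1 and Srm, enzymes of polyamine synthesis, rose by 1.46 ± 0.14 and 1.40 ± 0.18, and Rrp12 rose by 0.96 ± 0.14. In WT 3, 29 of the 30 genes were higher than in the mean of WT 1 and 2, by a median of 0.32 log2 units. Myc itself rose from 65.9 ± 10.5 to 111 ± 13.5 CPM (log2 fold change 0.75 ± 0.12 SE, adjusted p = 0.00176). Among glycolysis and nutrient transport genes 19 of 25 rose and 2 fell, the same counts as adjusted over the list alone (median 0.72, camera adjusted p = 1.00e-09, adjusted p = 0.120 with an estimated correlation). The lactate exporter gene Slc16a3, the amino acid transporter gene Slc7a5 and the glycolytic enzyme gene Gapdh rose by 1.82 ± 0.22, 1.78 ± 0.28 and 1.29 ± 0.12. The 2 genes that fell, Slc3a2 and Bnip3, were named after their values were seen, and the lower count was 0 without WT 1, WT 2 or Eumyc 1 and 1 without Eumyc 2 or Eumyc 3.

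Nuclear genes of oxidative phosphorylation rose in 23 of 30 cases and fell in none, or 24 adjusted over the list alone (median 0.31, camera adjusted p = 0.000111, adjusted p = 0.472 with an estimated correlation). Cox5a, Uqcrfs1 and Atp5b, subunits of the respiratory chain and ATP synthase, rose by 0.61 ± 0.10, 0.58 ± 0.07 and 0.58 ± 0.07. In the sterol and fatty acid synthesis list 15 of 22 genes rose and 1 fell, and adjusted over the list alone the counts were the same (median 0.46, camera adjusted p = 0.000560, adjusted p = 0.472 with an estimated correlation). The sterol synthesis genes Cyp51 and Fdft1 rose by 1.25 ± 0.19 and 0.98 ± 0.11. The unfolded protein and integrated stress response list had 15 of 21 genes higher and 3 lower, and the same counts adjusted over the list alone (median 0.56, camera adjusted p = 7.05e-05, adjusted p = 0.387 with an estimated correlation). The serine synthesis genes Psat1 and Phgdh rose by 1.52 ± 0.19 and 1.14 ± 0.15, and the stress-induced transcription factor gene Ddit3 fell by 0.81 (SE 0.13).

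Genes that define NK cells fell more often than they rose. Of the 24 NK identity genes 11 fell, 3 rose and 10 did not pass, with the same counts adjusted over the list alone (median -0.21, camera adjusted p = 0.0108, adjusted p = 0.387 with an estimated correlation). Klre1 and Klrd1, which encode lectin-like receptor chains, had log2 fold changes of -0.82 ± 0.09 and -0.70 ± 0.07, and Cd160 rose by 1.18 ± 0.11. The receptor genes Ncr1 and Klrb1c, the latter encoding NK1.1, fell by 0.28 (SE 0.07) and 0.48 (SE 0.06). The count of identity genes that rose was 5 without WT 3. In the NK terminal maturation list 7 of 16 genes fell and 3 rose, or 9 and 4 adjusted over the list alone (median -0.28, camera adjusted p = 0.0160, 0.0655 with fry, and adjusted p = 0.536 with an estimated correlation). S1pr1 fell by 1.51 (SE 0.09), S1pr5 by 0.99 (SE 0.13) and the transcription factor gene Zeb2 by 0.70 (SE 0.14). Klrg1, a receptor of mature NK cells, rose by 0.65 ± 0.10, and Itgam was at 161 ± 21.3 and 130 ± 18.7 CPM with an adjusted p of 0.0670. The Itgam symbol belongs to 2 overlapping gene identifiers, so its value is uncertain, and it passed without WT 3 (log2 fold change -0.40, adjusted p = 0.0171) and without Eumyc 1 (-0.41, adjusted p = 0.0183). Itgam also passed with DESeq2 (adjusted p = 0.0469), total counts (0.0371), upper quartile scaling (0.0402), no filter (0.0495), voom quality weights (0.0257), a replicate block (0.00465) and at equal depth (0.0294), always lower in Eumyc. The count of maturation genes that rose was 1 without WT 2.

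The transcription factor genes Eomes and Tbx21 stood at 637 ± 62.6 and 554 ± 9.83 CPM in WT and at 486 ± 53.5 and 505 ± 38.8 CPM in Eumyc. Eomes fell by 0.39 (SE 0.10, adjusted p = 0.0126), and its adjusted p was 0.0525 without WT 1 and 0.0526 without WT 2. Tbx21 did not pass (adjusted p = 0.137). Of 30 NK transcription factor genes 8 rose and 10 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.942). Irf4 and Id3 rose by 2.29 ± 0.16 and 1.86 ± 0.22. The NK immaturity list did not pass either (adjusted p = 0.886), with 5 of 17 genes higher and 4 lower over all genes and adjusted over the list alone, and 8 higher without WT 3. Thy1, Cd69 and Tox rose by 1.03 ± 0.22, 0.68 ± 0.15 and 0.67 ± 0.11, and Cd27 fell by 0.39 (SE 0.06). The leukocyte gene Ptprc was at 4624 ± 190 and 4383 ± 368 CPM and did not pass (adjusted p = 0.495).

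**Figure D2:**
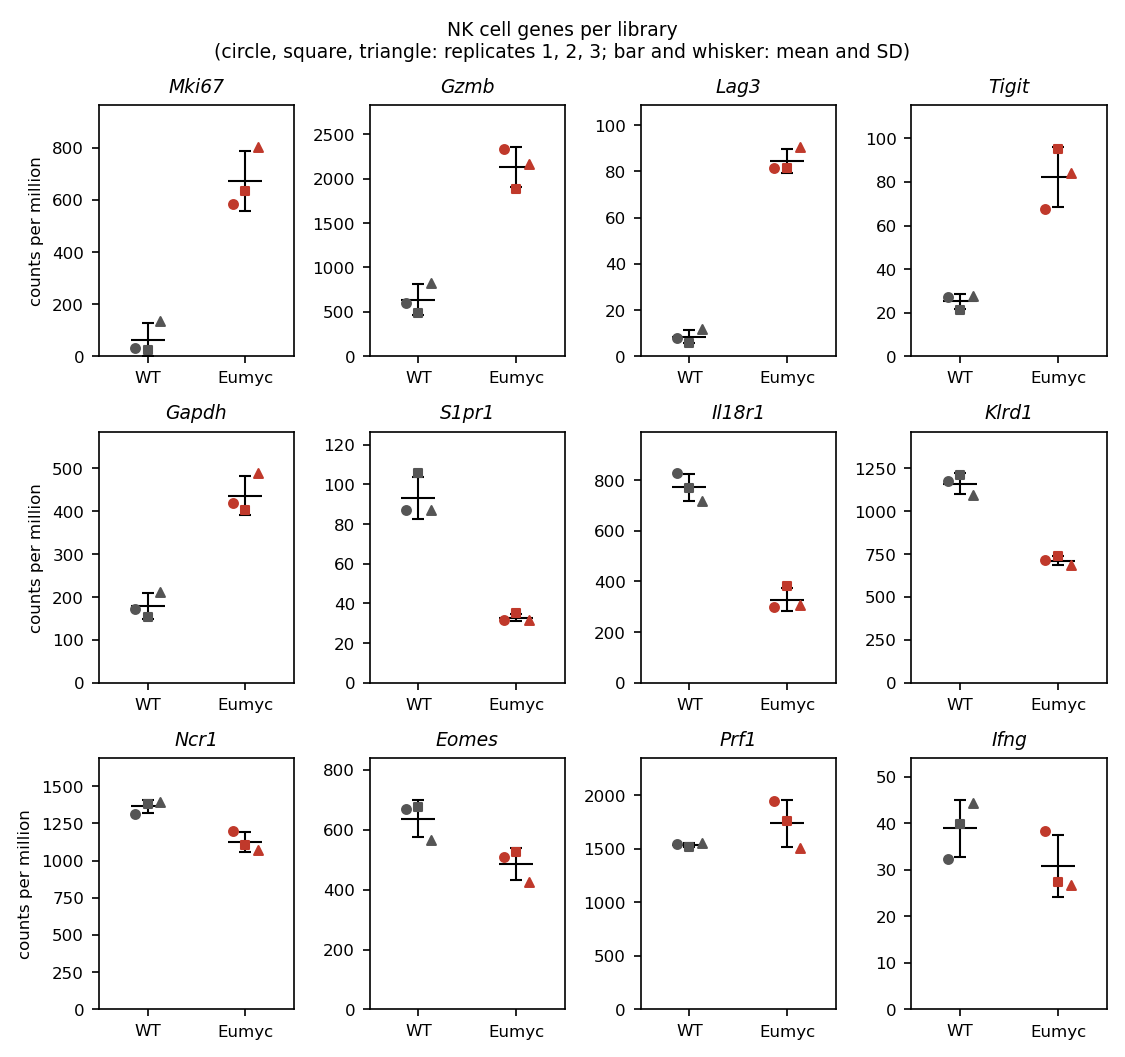
TMM-scaled CPM (vertical axis, from 0) of 12 genes in the 3 WT and 3 Eumyc libraries, with the mean and SD of each group. WT 3 is the WT library with the highest Mki67 value (136 CPM), and all 3 Eumyc libraries exceed it.

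Effector genes moved unevenly. In the cytotoxic granule and death ligand list 7 of 20 genes rose, 3 fell and 10 did not pass, and 8 rose and 3 fell adjusted over the list alone (median 0.12, camera adjusted p = 0.0228, adjusted p = 0.387 with an estimated correlation). Gzmb rose by 1.74 ± 0.18, the granzyme genes Gzmc and Gzmk by 2.47 ± 0.52 and 2.00 ± 0.15, and Tnfsf10, which encodes the death ligand TRAIL, by 1.81 ± 0.11. Gzmc had a log2 fold change of 3.12 without WT 3. Cytokine and chemokine genes did not pass as a list (camera adjusted p = 0.167), with 7 of 17 higher and 3 lower over all genes and adjusted over the list alone, and with 11 higher without WT 3. Ccl9 and Ccl4 rose by 1.99 ± 0.28 and 1.61 ± 0.18, and Vegfa fell by 1.98 (SE 0.21). Of 15 cytokine and chemokine genes with a mean of at least 1 CPM in Eumyc, 12 were higher in Eumyc 1 than in the mean of Eumyc 2 and 3. The median was 0.40 log2 units, with Ccl9 at 0.70 and Ccl4 at 0.44. Activating receptor signalling genes, 5 of 25 higher and 5 lower over all genes and adjusted over the list alone, did not pass (camera adjusted p = 0.990), and 8 were higher without WT 3. Klrc2 fell by 0.86 (SE 0.12), and Crtam and Plcg2 rose by 0.79 ± 0.10 and 0.63 ± 0.06. Of the 12 Ly49 receptor genes 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.783). Klra10 and Klra13-ps fell by 1.40 (SE 0.21) and 1.00 (SE 0.10), while Klra2 rose by 3.54 ± 0.37. These near-identical genes share reads, so their single values are uncertain.

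Inhibitory receptor and exhaustion genes rose in 15 of 27 cases and fell in 2, or 16 and 2 adjusted over the list alone (median 0.64, camera adjusted p = 8.97e-06, adjusted p = 0.0690 with an estimated correlation). Lag3 rose by 3.34 ± 0.20 and Tigit by 1.71 ± 0.15, with all 3 Eumyc libraries above all 3 WT libraries. Havcr2, which encodes TIM-3, rose by 4.16 ± 0.36 and the nuclear receptor gene Nr4a1 by 2.53 ± 0.33. Both were higher in Eumyc 1 than in the mean of Eumyc 2 and 3, by over 1 log2 unit (1.01 for Havcr2), where Lag3 differed by -0.08 and Tigit by -0.40. The 13 risen members of the monocyte and macrophage list were higher in Eumyc 1 by a median of 0.92 log2 units, and Klra2 by 0.92. Pdcd1, which encodes PD-1, was at 0.0481 ± 0.0551 CPM in WT, a total of 5 counts, and at 1.86 ± 0.164 CPM in Eumyc (log2 fold change 4.88 ± 0.51 SE, adjusted p = 0.000289), and its log2 fold change was 6.21 without WT 2. The count that fell was 1 without WT 1 or WT 2.

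ILC1 and tissue residency genes, named for the tissue-bound relatives of NK cells, rose in 16 of 19 cases and fell in 1, also adjusted over the list alone (median 1.52, camera adjusted p = 3.15e-07, adjusted p = 0.315 with an estimated correlation). Gpr55 rose by 3.23 ± 0.21 and Hic1 by 1.98 ± 0.15, and the collagen-binding integrin gene Itga1 rose by 1.74 ± 0.18. In Eumyc 1 only 6 of the 19 genes were above the mean of Eumyc 2 and 3, with a median of -0.49 log2 units. Among cytokine receptor and STAT genes 9 of 27 rose and 9 fell, or 11 and 9 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.954). Il2ra and Il21r rose by 1.97 ± 0.38 and 1.56 ± 0.10, and Il18r1 fell from 771 ± 54.8 to 329 ± 47.1 CPM. Trafficking and adhesion genes did not pass as a list (camera adjusted p = 0.150, but 0.0365 with fry), with 6 of 23 higher and 7 lower, 7 and 8 adjusted over the list alone, and 11 lower without WT 3. The chemokine receptor gene Cxcr4, which retains cells in bone marrow, fell by 1.69 (SE 0.20).

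Type I interferon response genes rose in 17 of 31 cases and fell in none, with the same count adjusted over the list alone (median 0.76, camera adjusted p = 0.00420, adjusted p = 0.660 with an estimated correlation). Ifi27l2a, Isg15 and Oasl2 rose by 2.33 ± 0.45, 1.54 ± 0.31 and 1.54 ± 0.47. The count that rose was 6 without WT 1, 6 without WT 2 and 8 without Eumyc 1, and the list did not pass with fry (adjusted p = 0.136). Oasl2 lost its call without WT 1, WT 2 or Eumyc 1 (adjusted p = 0.0958, 0.103 and 0.0592), with a log2 fold change of 0.87 in the last case, and with voom (0.0769) and voom quality weights (0.0736). All 31 genes were higher in Eumyc 1 than in the mean of Eumyc 2 and 3, by a median of 0.62 log2 units, and 30 of 31 were higher in WT 3 than in the mean of WT 1 and 2, by a median of 0.61. In the interferon-gamma response list 16 of 26 genes rose and 1 fell, also adjusted over the list alone (median 0.44, camera adjusted p = 0.00125, adjusted p = 0.536 with an estimated correlation). Of these genes 25 of 26 were higher in Eumyc 1 than in the mean of Eumyc 2 and 3, by a median of 0.18 log2 units, and 24 of 26 in WT 3 than in the mean of WT 1 and 2, by 0.33. Gbp6, Gbp2 and Psmb8 rose by 1.26 ± 0.34, 0.72 ± 0.11 and 0.54 ± 0.11, and Gbp6 had an adjusted p of 0.0620 without WT 1. The single lower call, Gbp7, was named after its value was seen, and the lower count was 0 without WT 1, WT 3, Eumyc 2 or Eumyc 3 and 2 without Eumyc 1.

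Immediate early and dissociation stress genes, which change within minutes of cell handling or stimulation, fell in 14 of 24 cases and rose in 5, also adjusted over the list alone (median -0.67, camera adjusted p = 0.00151, adjusted p = 0.472 with an estimated correlation). Fos fell from 48.8 ± 13.2 to 6.52 ± 0.835 CPM, whereas Egr1, another gene of this class, rose from 19.6 ± 7.01 to 70.1 ± 8.08 CPM. All 23 list genes with a mean of at least 1 CPM in Eumyc were higher in Eumyc 1 than in the mean of Eumyc 2 and 3. The median was 0.22 log2 units. Of 24 apoptosis and p53 target genes 9 rose and 4 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 0.0231, 0.0844 with a filter of 3 CPM, and adjusted p = 0.472 with an estimated correlation). Bcl2a1d and Pmaip1, members of the Bcl-2 family, rose by 3.42 ± 0.24 and 1.74 ± 0.17, and Bak1 rose by 1.01 ± 0.08. In Eumyc 1 they were above the mean of Eumyc 2 and 3 by 0.61, 0.60 and 0.16 log2 units. Bcl2a1d has near-identical copies, so its value is uncertain.

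By the rule for extreme genes, the 8 highest log2 fold changes were those of Ceacam1, Fabp4, Thbd, Ldlrad3, Ace, Fcgr4, Arhgef10l and Hp, between 6.13 and 6.82. Fcgr4, an antibody receptor of myeloid cells, stood at 1.66, 1.70 and 1.32 CPM in WT and at 195, 65.7 and 108 CPM in Eumyc. Ace, which encodes a peptidase, rose from 1.87 ± 0.562 to 139 ± 77.1 CPM. All 8 were higher in Eumyc 1 than in the mean of Eumyc 2 and 3, by 0.56 to 1.48 log2 units. The WT group held 9 counts of Fabp4, 11 of Thbd, 13 of Ldlrad3, 23 of Hp and 30 of Ceacam1, and the log2 fold change of Thbd was 7.89 without WT 1 and that of Hp was 7.38 without WT 3. Ceacam1 was at 7.43 without WT 1, and Arhgef10l at 6.87 without WT 3 and 5.54 without Eumyc 1. The 8 lowest were Fos, Tbx6, St5, Abca1, Cym, Vegfa, Cdh22 and Per3, between -2.91 and -1.96. St5 fell from 104 ± 31.9 to 23.2 ± 5.21 CPM and the cholesterol exporter gene Abca1 from 143 ± 46.3 to 32.7 ± 6.78 CPM, and the circadian clock gene Per3 fell by 1.96 (SE 0.17) on the log2 scale.

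The next comparison asked how much signal of other cell types each library held, since the tumour was a B cell lymphoma and the Eumyc sort also took cells that the CD49b beads had not bound. Markers of several other blood cells were higher in Eumyc. The B cell list summed to 350 ± 13.2 CPM in WT and 666 ± 254 CPM in Eumyc (SD, n = 3 each), with Eumyc 3 at 956 CPM. The antibody heavy chain gene Ighm was at 181 ± 3.54 and 401 ± 208 CPM. In WT most of the list sum came from Ighm and from Cd72, at 134 CPM. The sum therefore does not measure how many B cells a library held. For the list sum, all 3 Eumyc libraries exceeded all 3 WT libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The difference of 316.5 CPM was 171.5 CPM without Eumyc replicate 3, and Ighm had an adjusted p of 0.0533 without WT 1.

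Of the B cell list 16 of 21 tested genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 2.72e-07, adjusted p = 0.0690 with an estimated correlation), and 1 fell without WT 1, WT 2 or Eumyc 3. Only 5 of the 30 listed genes reached a mean of 3 CPM in WT, so others could enter the test through the Eumyc libraries alone. Cd72, which fell, was at 134 ± 7.96 CPM in WT and 96.0 ± 6.26 CPM in Eumyc. Plasma cell genes rose in 11 of 14 cases and fell in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 1.69e-11, adjusted p = 0.0564 with an estimated correlation), with Xbp1 higher by 0.56 ± 0.07 and Prdm1 lower by 0.52 (SE 0.08). Only 3 of the 15 listed plasma cell genes reached a mean of 3 CPM in WT, so the same limit holds. Most of the plasma cell list sum in WT, 236 CPM, came from Xbp1 and Prdm1, at 97.4 and 127 CPM. Prdm1 is also in the NK terminal maturation list. Class II antigen presentation genes rose in 8 of 10 cases, also adjusted over the list alone (camera adjusted p = 0.000203, adjusted p = 0.428 with an estimated correlation), and Cd74 and H2-Aa rose by 1.84 ± 0.27 and 2.09 ± 0.26. In WT 3, 7 of 9 class II genes were higher than in the mean of WT 1 and 2, with a median of 0.65 log2 units. The 22 T cell genes did not pass as a list (camera adjusted p = 0.0720, but 0.0362 without WT 2, 0.0250 without Eumyc 1, 0.0397 with a replicate block, 0.0152 with no filter on low counts and 0.0204 with fry), with 7 higher and 3 lower, also adjusted over the list alone. Trbc1 was at 261 ± 15.3 and 261 ± 10.4 CPM, and Trbc2 rose by 0.48 ± 0.09. With GC and length trends removed Trbc2 did not pass (log2 fold change 0.23, adjusted p = 0.0599) and Trbc1 was lower (-0.23, adjusted p = 0.0302).

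Monocyte and macrophage genes rose in 13 of 24 cases and fell in 3, also adjusted over the list alone (median 0.51, camera adjusted p = 0.000611, adjusted p = 0.453 with an estimated correlation). The list summed to 1266 ± 12.9 CPM in WT and to 2485, 1780 and 1892 CPM in Eumyc 1, 2 and 3, and 20 of its 24 genes reached 3 CPM in WT. Most of the WT sum came from Ccr2, at 832 CPM in WT and 978 CPM in Eumyc. Csf1r, the receptor of a macrophage growth factor, rose by 2.42 ± 0.30, and Ccr2 rose by 0.23 ± 0.08 (adjusted p = 0.0457), a call lost without WT 1, WT 2, Eumyc 1 or Eumyc 2 (adjusted p = 0.123, 0.115, 0.0988 and 0.0960) and with total counts (0.0737) or upper quartile scaling (0.0786). The count that fell was 1 without WT 1, WT 2, Eumyc 1 or Eumyc 2. Neutrophil genes summed to 6.59 ± 1.63 CPM in WT and 101 ± 24.4 CPM in Eumyc. Of the 21 listed, 0 reached a mean of 3 CPM in WT. Genes could thus enter the test through the Eumyc libraries alone, which leaves little room for a fall. Of 17 tested, 16 rose, also adjusted over the list alone (camera adjusted p = 1.24e-10, adjusted p = 0.262 with an estimated correlation). Their median log2 fold change was 5.14, or 4.83 with the 4 genes at 0 in WT set to a bound of 3 counts over the group, and was 4.40 without WT 2 and 6.18 without WT 3. In WT 3, 11 of 13 neutrophil genes were above the mean of WT 1 and 2, with a median of 1.54 log2 units. S100a9 and Csf3r rose by 4.77 ± 0.51 and 2.95 ± 0.34, and S100a9 was at 4.12 without WT 2 and 5.59 without WT 3.

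Erythroid genes rose in 17 of 19 cases and fell in 1, or 18 and 1 adjusted over the list alone (median 1.96, camera adjusted p = 1.73e-12, adjusted p = 0.0772 with an estimated correlation), and the median was 2.80 without WT 2. The lower count was 0 without WT 2 or any 1 Eumyc library. Only 5 of the 19 erythroid genes reached a mean of 3 CPM in WT. Car2 rose by 1.38 ± 0.08 and Hbb-bs by 1.21 ± 0.29. Most of the erythroid list sum in WT, 205 CPM, came from Car2, at 151 CPM. Dendritic cell genes rose in 8 of 15 cases and fell in 1, or 9 and 1 adjusted over the list alone (median 1.04, camera adjusted p = 0.00842, 0.146 with a filter of 3 CPM, 0.0599 at equal depth, and adjusted p = 0.380 with an estimated correlation). Itgax, which NK cells also express, rose from 769 ± 48.6 to 1215 ± 55.2 CPM, and Runx2 did not pass (adjusted p = 0.355). The basophil and mast cell list (3 of 10 higher, 1 lower) and the megakaryocyte list (4 of 9 higher, 3 lower), both with the same counts adjusted over the list alone, did not pass camera (adjusted p = 0.672 and 0.243), though the megakaryocyte list passed with fry (0.0122). The basophil list had 0 lower without WT 1, WT 2, Eumyc 1 or Eumyc 3, and the megakaryocyte list 1 lower without any of these. Prss34 rose by 3.45 ± 1.09 and Cpa3 fell by 0.68 (SE 0.23), with calls that were lost without WT 1, WT 2 or Eumyc 1 (Prss34 at adjusted p = 0.0802, 0.0889 and 0.0886, and Cpa3 at 0.122, 0.0764 and 0.111), and Cpa3 also without Eumyc 3 (0.111). Prss34 was also lost with DESeq2 (0.0804), voom (0.129) and voom quality weights (0.0998), and Cpa3 with a replicate block (0.0508), no filter (0.0623) and at equal depth (0.0746). The log2 fold change of Prss34 was 2.68 without WT 2, 4.10 without WT 3 and 2.46 without Eumyc 1. Itgb3 and Nrgn rose by 1.09 ± 0.10 and 0.86 ± 0.12. The stroma and endothelium list had only 4 tested genes, too few for camera, of which 2 rose, or 3 adjusted over the list alone, and 4 of 6 tested rose without WT 1 or WT 3. Pecam1 rose by 0.84 ± 0.11, and Pdgfrb had 0 counts in WT and 98 in Eumyc, at least 14.9-fold higher against 3 counts over the WT group.

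**Figure D3:**
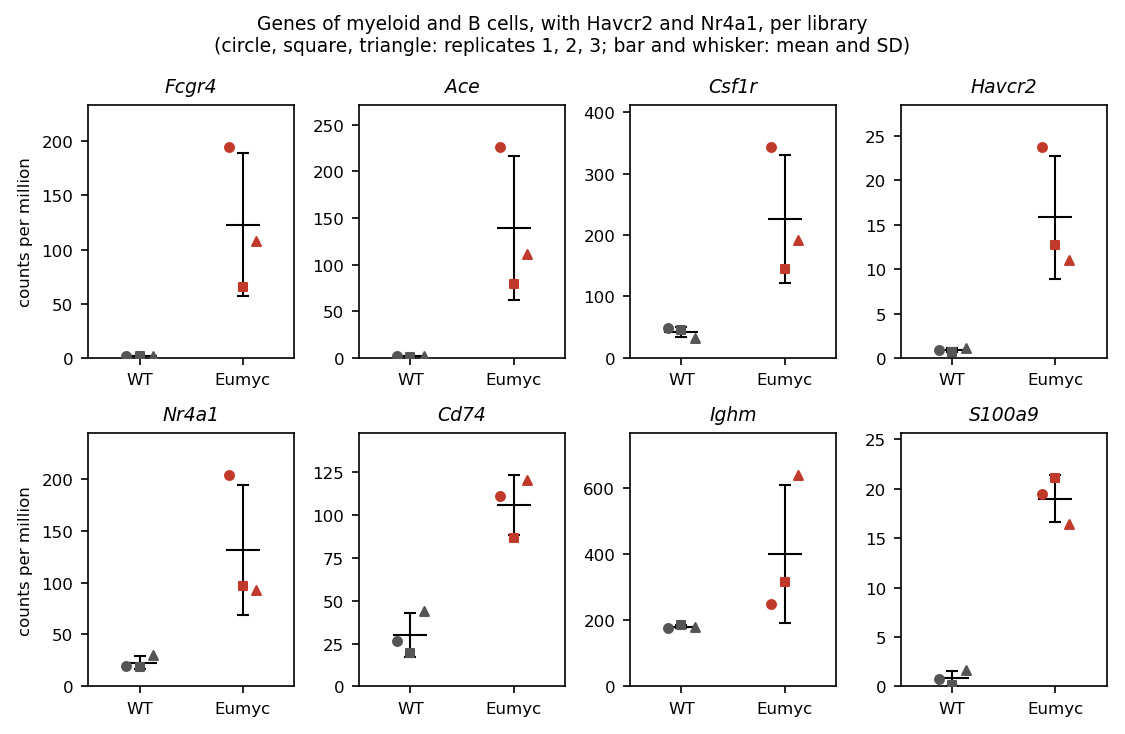
TMM-scaled CPM (vertical axis, from 0) of 8 genes in each WT and Eumyc library, with the mean and SD of each group. Fcgr4, Ace, Csf1r, Havcr2 and Nr4a1 share Eumyc 1 as their highest library, and Ighm is highest in Eumyc 3 (638 CPM).

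The last comparison set these calls beside the authors' deposited table, which tests the same contrast on the same libraries and so is not independent evidence. The authors' deposited comparison covers 10288 genes with an adjusted p, of which 6165 passed 0.05, 3134 higher and 3031 lower in Eumyc. Among genes in both, 3037 of those higher and 2790 of those lower in the authors' deposited table were called in the same direction by edgeR, or 94.5% in all, and 0 in the opposite direction. Unrelated lists of these sizes would share 928.5 and 824 genes. The log2 fold changes correlated with those of the authors' deposited table across genes (Pearson r = 0.965). Fold changes were smaller in the authors' deposited table for 98 of the 108 named genes it holds, and whether they were shrunk is not given in the sources used here. Lag3, Gzmb and S1pr1 were at 3.11, 1.56 and -1.49 there on the log2 scale, close to the edgeR values of 3.34, 1.74 and -1.51. Other genes differed more, with Mki67 at 1.44 (3.42 with edgeR), Rrm2 at 1.39 (3.15), Uhrf1 at 1.21 (2.80), Hmmr at 2.01 (4.63), Fcgr4 at 4.47 (6.26) and Hp at 1.74 (6.13). These 9 were chosen after their values were seen.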

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

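Thinning and the removal of GC and length trends were chosen after seeing the data. Between 5868 and 7907 genes were called when single libraries were left out, with 3252 to 4284 higher and 2616 to 3623 lower, and 23 or 24 gene lists. Other tools, scalings and filters called 6486 to 8113 genes, and of the 7549 calls DESeq2 kept 94.9%, thinned counts 86.8% and trend-corrected counts 90.5%, all in the same direction. The balance of directions turned with 2 scalings, from 3973 higher and 3576 lower to 3628 and 3957 with total counts and to 3633 and 4002 with the upper quartile. Against a 1.5-fold change 1828 genes passed, 1260 higher and 568 lower, since small changes cannot pass that test. With an estimated correlation 0 lists passed, and without an estimate 21 to 25 lists did. The estimates of the plasma cell and inhibitory receptor lists, -0.0107 and -0.00297, lay below the preset 0.01. Their unadjusted camera p still went from 2.04e-12 to 0.00171 and from 2.72e-06 to 0.00623. This argues against correlated genes as the reason for these 2 lists, and the reason was not tested further. For the other lists too, a p with an estimated correlation need not reflect correlation alone. The apoptosis and dendritic cell lists lost their call with the 3 CPM filter (adjusted p = 0.0844 and 0.146), the dendritic cell list also at equal depth (0.0599), and NK terminal maturation and type I interferon response with fry (0.0655 and 0.136), and the cause was not tested. The T cell list newly passed in 5 of the 15 alternatives without the estimated correlation, and the trafficking and megakaryocyte lists with fry (0.0365 and 0.0122). No named gene or list that passed in either setting reversed, although some lists that did not pass had medians near 0 or directions that changed sign. Over all alternatives 2141 values of named genes stayed on their side of the threshold, 63 fell short of it and 12 newly passed it. Of the 63, 34 came from the test against a 1.5-fold change, which asks a stricter question. The B cell list difference ran from 171.5 to 409.4 CPM when single libraries were left out and was 334.5 CPM with mitochondrial and ribosomal protein genes outside the total. DESeq2 shared 93.5% of the authors' calls. The WT libraries are the shallower ones, and how depth affects genes with few WT counts was not tested separately.

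Same-numbered libraries do not share a stated animal, litter or day. Their deviations from the group means correlated at 0.0404, 0.0985 and 0.126 across genes, not all over 0.1, although each sample correlated best with its own number, which is a hint from the data and not from the design. A replicate block moved the count of changed genes from 7549 to 7860.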

Other observations

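The test of the bead fraction was chosen after its result was seen. The second monocyte list and the clock lists were drawn up after the values of Fcgr4, Ace, Csf1r, Lyz2, Per3, Dbp and Nr1d2 had been seen, and their tests were written down before the results were known. Antigen receptor genes were counted as groups, and these counts were not tested against other genes. Over all 15458 tested genes 3973 were higher and 3576 lower. Of 42 tested immunoglobulin segments and constant genes 35 were higher and 1 lower in Eumyc, and of 49 T cell receptor segments and constant genes 6 were higher and 16 lower. All immunoglobulin genes together took 198 ± 7.28 CPM in WT and 482, 614 and 1159 CPM in Eumyc 1, 2 and 3 (two-sided exact permutation p = 0.1, the smallest possible). Ighm alone was at 181 CPM in WT (TMM-scaled), so the other immunoglobulin genes held little of the WT sum. They could thus enter the test through the Eumyc libraries alone. The light chain gene Igkc, chosen after its values were seen, was at 51.2, 69.4 and 138 CPM in Eumyc 1, 2 and 3 and at 0.144, 0.298 and 1.98 CPM in WT.

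The circadian clock output genes Per3, Dbp and Nr1d2 fell by 1.96 (SE 0.17), 1.59 (SE 0.12) and 1.39 (SE 0.14). Of 7 further clock output genes 4 were lower, among them Tef by 1.24 (SE 0.12), 1, Bhlhe41, was higher and 2 did not pass, and whether these genes stand apart from others was not tested. Another time of day at harvest was predicted to raise genes of the opposite clock phase. Arntl, Clock and Cry1 had a median log2 fold change of -0.14 (Npas2 had too few counts). With 3 genes this cannot decide on the time of harvest. At equal depth the median over 9 of the 10 clock output genes, those still tested, was -1.23, where it had been -0.87. Thinning leaves the expected share of a gene in its library unchanged, so this cannot decide on greater depth in Eumyc. The 8 clock output genes with a mean of at least 1 CPM in Eumyc were all lower in WT 3 than in the mean of WT 1 and 2, by a median of 0.42 log2 units, and WT 3 held more mitosis transcripts. A link with cell division, a change in clock output with lymphoma and another time of harvest remain open. So do greater depth in Eumyc and a change in which cells were sorted.

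Myeloid genes rose in Eumyc, with Csf1r at 226 CPM, Lyz2 at 186 CPM and Fcgr4 at 123 CPM. A candidate explanation is monocytes among the sorted cells, although the gate on NK1.1 and against the T cell receptor would remove most of them. A second list of 25 monocyte genes, none in the fixed lists and 14 of them over 3 CPM in WT, had 23 genes higher (92%) and 0 lower, with a median log2 fold change of 2.32. In Eumyc 1, 24 of these 25 genes were above the mean of Eumyc 2 and 3, by a median of 0.95 log2 units, while the mitosis list differed by -0.29. At equal depth the median was 2.28. Thinning keeps each gene's expected share of its library, so this value was bound to stay close and cannot decide on depth. Expression of these genes in NK cells themselves remains untested.

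Of 19 ILC1 and tissue residency genes 16 rose and 1 fell, while Itga2, which encodes the CD49b protein bound by the beads, fell from 277 to 200 CPM (log2 fold change -0.47 ± 0.11 SE, edgeR adjusted p = 0.00750). The rises and the fall of Itga2 may follow from the unbound bead fraction, which was sorted for Eumyc and not for WT. This step is shared by all 3 Eumyc libraries and no WT library. The sort and the lymphoma therefore cannot be told apart, for these genes or for any other difference between the groups.

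For the number of changed genes, the 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 7549 genes with edgeR and 1 of the 10 splits, the real one, gave as many. The highest count of the other splits was 0, with up to 427 genes at an unadjusted p under 0.05, where the real split had 8680. Every other split mixes WT and Eumyc libraries, so the group difference widens its spread. Low counts were bound to follow and do not measure chance.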
